A study of Homo sapiens with 7 samples.

How the data were processed

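Each of the 7 samples is 1 single-colour array of total RNA labelled with Cy3, and the labels' protocols describe an Agilent Quick-Amp kit with an oligo-dT primer, RNA from an RNeasy kit with DNase, and NB4 cells taken back from HS-5 cells after co-culture. No sorting step is given in the sources used here. Basal samples were 3 and co-culture samples 4, numbered 1, 2, 3 and 3a. The deposited scanner files hold spot intensity on a linear scale, written by Agilent Feature Extraction 11.5.1.1 per the file headers, and the submitters' processing notes name the same program. The processed intensity is background-subtracted and without normalization between arrays, per the file headers. The authors also deposited a table of log2 values. In each of its columns, 99.4% to 99.6% of probes lie within 0.01 of the log2 processed signal minus 1 constant per array, and the reason the others differ was not tested. That constant puts the 75th percentile near 0 and the column medians at -3.86, -3.77 and -3.82 (basal) and -3.73, -3.64, -3.64 and -3.7 (co-culture). Genes are not centred in it and its direction is plain, so no property of its scale stays unknown. Flags for background, saturation and outliers (other columns) were used as deposited. Probe positions follow hg19, per the file headers.

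Control spots and spots marked as outliers were left out and the spots of a probe averaged, which gave 50599 probes. The main values were log2 processed intensity minus each array's 75th percentile. A probe was kept if it was well above background on every array of at least 1 group and had a value on every array (16 had an array without one), which left 27248. As depth, between 50.3% and 57.3% of probes per array were well above background. Arrays 3 and 3a were averaged before the fit. They differed less (median absolute deviation 0.108) than other pairs of co-culture arrays (0.196 to 0.244) or basal arrays (0.316 to 0.377). All arrays lie on 1 slide with 1 scan. Its first row holds the basal arrays and co-culture array 1, and its second row the other co-culture arrays. The scanner's own quality report marked co-culture array 1 for evaluation and the others as in range.

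Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, statmod 1.5.0, two-sided, Benjamini-Hochberg over kept probes, threshold 0.05), as 3 replicates against 3. A gene's probe was the one with the highest mean signal over all arrays. Of the kept probes, 19508 of 20076 with a RefSeq accession matched the current gene table (assembly GRCh38.p14, used for names only), 2688 took a newer symbol and the rest kept the file's name, giving 16578 genes. Y-linked genes and XIST were left out of the tables of genes (95 probes). The 30 gene lists were fixed before the data were examined, tested with camera (preset correlation 0.01; again with an estimated one) and fry, with at least 5 measured members required. A gene below background on every array of a group is given as "at least N-fold": the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own. Named genes followed a rule also fixed beforehand: the 12 largest increases and 12 largest decreases among genes past the threshold, at least 2-fold and with every co-culture array on one side of every basal array; up to 4 members per list past the threshold with the largest change; and the 5 fibroblast genes brightest in co-culture. On simulated data for this comparison over 27248 probes, 2% of probes changed 1.5-fold, 34% of those changed 2-fold, 76% at 4-fold and 86% at 8-fold were recovered, with 6 false calls. Only 50 probes were changed at each fold, far fewer than were called in the data, so these shares do not give the power here. In the simulation camera called the 1 shifted list and none of the other 29 over 16578 genes. Its noise was independent between probes, so this does not test camera where genes are correlated.

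The stromal index is the mean log2 deviation from the co-culture mean of fibroblast list genes that rose, were below background on all basal arrays and above it on all co-culture arrays. A gene's slope is that of its deviations on the index over the 3 co-culture replicates, and index genes were set against the other index genes. It was chosen after seeing the data, as was the comparison of probe pairs by position. Alternatives were normexp background correction (offset 50), quantile and median scaling, the deposited table, other filters, other treatments of arrays 3 and 3a, a replicate block, the slide row, each replicate left out, other variance settings, array weights, other thresholds and other choices of a gene's probe. Removal of the trend over probe position (lowess per array) and the 5'-most probe of each gene were added after seeing the data.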

Results

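Gene expression was measured on 7 single-colour oligonucleotide arrays in NB4, an established acute promyelocytic leukaemia line that carries the PML-RARA fusion. The basal group held 3 arrays of NB4 cells grown alone. The co-culture group held 4 arrays, numbered 1, 2, 3 and 3a, of NB4 cells recovered after 48 hours with HS-5, a human bone marrow stromal line that secretes cytokines. Arrays 3 and 3a share a number and were averaged, so each comparison set 3 co-culture replicates against 3 basal replicates. On each array 50599 probes were read, of which between 50.3% and 57.3% were well above background, and no spot was saturated. Across probes, arrays correlated at 0.99 to 0.992 within the basal group, at 0.988 to 0.993 within the co-culture group and at 0.896 to 0.915 between the groups. The number of arrays limits the precision of every value below.

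The comparison asks how the transcriptome of promyelocytic leukaemia cells changes when they share a dish with marrow stroma, a setting the series ties to drug resistance. In the co-culture arrays, stromal matrix and cytokine transcripts and several genes of mature myeloid cells were far higher. Metallothioneins and a list of cell cycle inhibitors and p53 targets were moderately higher, and nearly every measured gene of ribosome biogenesis was lower. Of 27248 probes tested, 16023 passed an adjusted p of 0.05, with 6688 higher and 9335 lower in co-culture. A change of at least 2-fold was also met by 3962 of the higher and 4630 of the lower probes. Of the kept probes, 802 were not well above background on any basal array and all passed as higher, and 542 were so in co-culture only, of which 507 passed as lower. The filter keeps such probes for their signal in the other group, which largely sets their direction. The median change of all tested probes was -0.18 on the log2 scale, and other scalings moved it to between -0.31 and -0.05. Scaling to the array median gave 5799 higher and 11161 lower probes. A fit with the row of the slide as a term called 11032 probes. Its group effect rests on co-culture array 1 alone, the only one in the row of the basal arrays and the one marked for evaluation. Within the row that held all 3 basal arrays and 1 co-culture array, 9650 were called, and that lone co-culture array is assumed there to vary like the basal ones.

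Markers of stromal cells rose. Of 28 measured genes on the fibroblast and stromal matrix list, 23 rose and 1 fell, with a median log2 change of 3.17, or 2.9 with genes below background at their bound (camera adjusted p = 8.95e-10; adjusted p = 0.275 with an estimated correlation). The median was 1.51 with normexp and 0.94 over probes above background on all 7 arrays, where the list was still called. The largest fitted increase belonged to MMP1, interstitial collagenase, whose probe lies on chromosome 11 from 102660697 to 102660756 (hg19), although genes below background in basal cells may have risen more. MMP1 went from -3.99 ± 0.7 (SD, n = 3) in basal to 8.97 ± 0.4 (SD, n = 3) in co-culture relative to the 75th percentile, a change of 12.97 ± 0.37 (SE; limma adjusted p = 6.02e-06). MMP3, another matrix metalloproteinase, was at least 2000-fold higher. CCN1, a matricellular protein, was at least 409-fold higher, and COL1A2, a chain of type I collagen, at least 89.8-fold higher (probe on chromosome 7, 94058643 to 94058702). TFPI2, a protease inhibitor, rose by 12.33 ± 0.84 (SE), although only 1 of the 3 basal arrays measured it. The other genes with the largest increases were GNG11 (at least 285-fold), SERPINB3 (at least 314-fold), APP (at least 231-fold by its brightest probe), BEX3 (at least 289-fold), SERPINB4 (at least 226-fold), RND3 (at least 159-fold), ACKR3 (at least 146-fold) and CXCL1 (at least 158-fold by its brightest probe). A second probe of CXCL1, nearer the 5' end, rose by 2.98 ± 0.25 (SE), and that of APP, also below background in basal cells, was at least 1.9-fold higher. TGFBI and LOX on the list were at least 89.2-fold and at least 33.7-fold higher. Among the list members brightest in co-culture, COL6A1 rose by 4.93 ± 0.23 (SE) and SPARC by 2.66 ± 0.19 (SE). COL4A2 and IGFBP7 were already well above background in basal cells and did not pass the test, with log2 changes of 0.13 ± 0.16 and -0.21 ± 0.23 (SE). That of IGFBP7 changed sign to 0.09 under quantile scaling, and COL4A2 passed under it at 0.46.

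Cytokines and growth factors known from HS-5 cells rose in parallel. Of 23 measured, 18 rose and 2 fell, and adjusted over the list alone 18 rose and 3 fell, with a median log2 change of 5.1, or 3.7 with bounds (camera adjusted p = 2.18e-07; adjusted p = 0.232 with an estimated correlation). IL6 was at least 376-fold higher (probe on chromosome 7, 22771207 to 22771266), GREM1, an antagonist of bone morphogenetic proteins, at least 86.9-fold, and CSF3, which encodes granulocyte colony-stimulating factor, at least 68.5-fold. Signal of many, but not all, stromal genes differed between co-culture replicates in a shared proportion. Over 8 fibroblast genes below background in every basal array and above it in every co-culture array, an index of their mean log2 signal stood at -0.41 in replicate 1, -0.03 in replicate 2 and 0.44 in replicate 3 around the co-culture mean. COL1A1 was the 1 index gene with a negative slope on the others, at -0.22. Regressed on this index over the 3 replicates, the 9 cytokine genes below background in basal cells had a median slope of 0.83, with IL1A at 0.33 and CXCL6 at -0.79. Of the 21 fibroblast genes at least 2-fold higher, 66.7% had a slope over 0.5. The 12 genes with the largest increases had slopes from 0.82 to 1.65. Among all genes at least 2-fold higher, the median slope was 0.89 for the 497 below background in basal cells and 0.01 for the 1596 above background on every basal array. A constant basal signal lowers a gene's slope even where all of its rise follows the index, so these medians are not like for like.

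**Figure D1:**
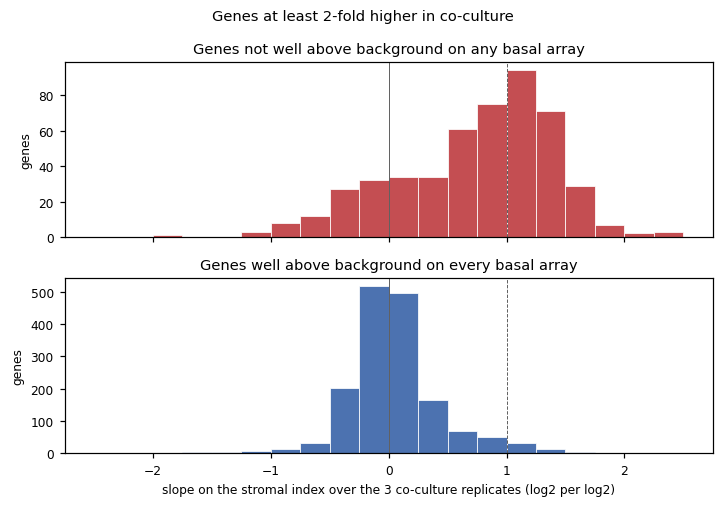
Number of genes (vertical axis) by slope of their log2 signal on the stromal index over the 3 co-culture replicates (horizontal axis), for genes at least 2-fold higher in co-culture with an adjusted p under 0.05. The 497 genes not well above background on any basal array (upper panel) have a median of 0.89 and the 1596 well above background on every basal array (lower panel) a median of 0.01. The solid line marks 0 and the dashed line 1. A constant basal signal lowers the slope even where all of a rise follows the index, so the panels are not like for like.

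Several genes of maturing myeloid cells rose in co-culture while granule genes went both ways. On the myeloid maturation list, 11 of 20 measured genes rose and 4 fell, with the same counts adjusted over the list alone and a median log2 change of 1 (camera adjusted p = 0.00693; adjusted p = 0.41 with an estimated correlation). TGM2, a transglutaminase induced as NB4 cells differentiate, was at least 27.4-fold higher (probe on chromosome 20, 36766446 to 36766505). NCF1, the p47phox subunit of the phagocyte oxidase, rose from 0.54 ± 0.03 to 6.23 ± 0.09 (SD, n = 3 each), and the integrin chains ITGAX (CD11c) and ITGAM (CD11b) rose by 3.75 ± 0.23 and 3.18 ± 0.16 (SE) on the log2 scale. NCF1 has near-identical pseudogenes that its probes cannot exclude. CAMP, CYBB, SPI1 and CEACAM1 were the 4 that fell. The 10 members at least 2-fold higher had a median slope on the stromal index of 0.08. Of 19 measured promyelocyte genes, 5 rose and 7 fell, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.986). Its test leaned upward while its median of -0.2 and mean of -0.19 were negative. CTSG, the azurophil granule protease cathepsin G, fell by 5.4 ± 0.27 (SE) on the log2 scale, from 7.07 ± 0.57 to 1.67 ± 0.04 (SD, n = 3 each; adjusted p = 1.74e-05; probe on chromosome 14, 25042788 to 25042847). The brighter of 2 probes of MYB, a progenitor transcription factor, fell by 1.8 ± 0.16 (SE). Over the alternatives, among them other choices of probe, the change of MYB ran from -1.93 to -0.78. SRGN, the granule proteoglycan serglycin, rose by 1.51 ± 0.19 (SE), and the receptor KIT was at least 3.42-fold higher.

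**Figure D2:**
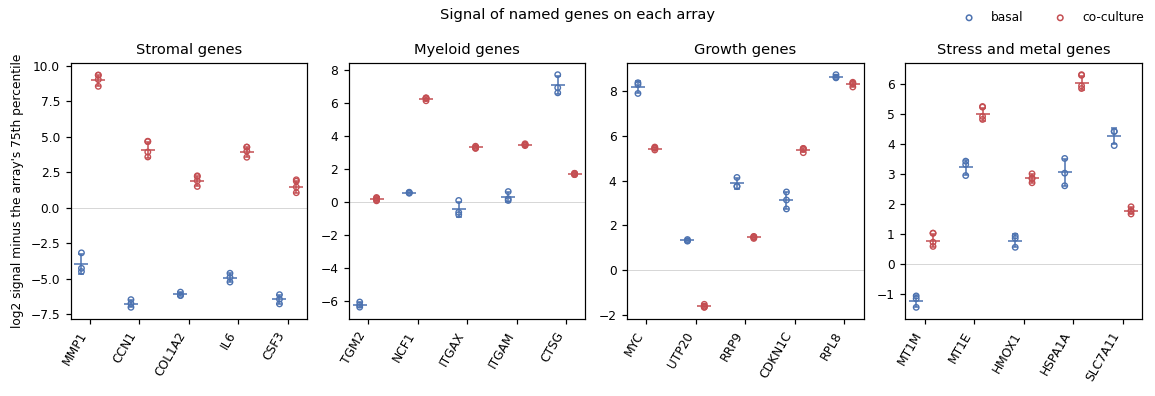
Signal of 20 named genes, as log2 signal minus the array's 75th percentile (vertical axis), on each array (circles), with the mean and SD over 3 replicates per group (bars; co-culture arrays 3 and 3a averaged first). Basal values of CCN1, COL1A2, IL6, CSF3 and TGM2 were not well above background, and CTSG went from 7.07 in basal to 1.67 in co-culture.

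Targets of inflammatory signalling changed unevenly. Of 31 measured NF-kB targets, 20 rose and 7 fell, or 20 and 8 adjusted over the list alone (median log2 change 1.26; camera adjusted p = 0.000127; adjusted p = 0.232 with an estimated correlation). The list shares 7 measured genes with the HS-5 cytokine list, including CXCL1 and IL6. PTGS2, the inducible cyclooxygenase, was at least 44.3-fold higher, and CXCL3 rose by 6.55 ± 0.61 (SE), measured on 1 of 3 basal arrays. The 10 risen members outside the cytokine list had a median slope of 0.09 on the stromal index, with 20% over 0.5, among them PTGS2 at 1.41. CXCL3, on both lists, had a slope of 0.62. Of 33 interferon-stimulated genes, 17 rose and 5 fell, in equal numbers adjusted over the list alone (median 0.69; camera adjusted p = 0.00336; adjusted p = 0.502 with an estimated correlation). IFI6 rose by 4.22 ± 0.32, IFI44 by 4.1 ± 0.23 and the guanylate-binding protein gene GBP2 by 3.91 ± 0.12 (SE), and GBP1 was at least 3.91-fold higher. The 13 interferon genes at least 2-fold higher had a median slope of -0.12, and IFI44 had one of 0.83. Among 23 JAK-STAT3 genes, 6 rose and 8 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.742), with a median of 0.13 against a mean of -0.08. BCL6 rose by 4.1 ± 0.31 and the kinase gene PIM1 by 2.89 ± 0.13 (SE), while the probe of FGL1 fell by 2.8 ± 0.24 (SE). The brightest probe of OSM, oncostatin M, fell by 3.42 ± 0.15 (SE), but its 5'-most probe had a change of 0.05 with an adjusted p of 0.923.

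Genes of ribosome biogenesis fell together. Of 24 measured, 23 fell and none rose, also adjusted over the list alone, with a median log2 change of -1.58 (camera adjusted p = 7.75e-07; adjusted p = 0.232 with an estimated correlation). UTP20, a processome component, fell by 2.93 ± 0.1 (SE), from 1.33 ± 0.03 to -1.6 ± 0.06 (SD, n = 3 each; probe on chromosome 12, 101777351 to 101777410). WDR43 fell by 2.47 ± 0.12 and RRP9 by 2.41 ± 0.14 (SE). The brightest probe of MYC, the transcription factor that drives this programme, fell by 2.76 ± 0.15 (SE; adjusted p = 2.34e-05; chromosome 8, 128753268 to 128753327). A second MYC probe, nearer the 5' end, had a change of 0.84 ± 0.48 (SE) and did not pass (adjusted p = 0.174). Of 30 ribosomal protein genes, 29 did not pass, and the list median was -0.1 (camera adjusted p = 0.822). With the trend over probe position removed, that median was -0.4 and the list was called lower (camera adjusted p = 0.00527). RPL8, at -0.36 ± 0.11 (SE), was the 1 that fell, and lost its call under several alternatives, such as quantile scaling (adjusted p = 0.0857). None passed when adjusted over the list alone.

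The medians of the cell cycle lists moved by smaller amounts. Cell cycle inhibitors and p53 targets, tested as 1 list, rose in 15 of 20 cases and fell in 2, also adjusted over the list alone (median 0.89; camera adjusted p = 0.000679; adjusted p = 0.404 with an estimated correlation). CDKN1C, encoding p57, rose by 2.25 ± 0.2 and TP53INP1 by 3.58 ± 0.37 (SE). PLK2 and CDKN1A rose by 4.26 ± 0.51 and 2.89 ± 0.58 (SE), with 2 and 1 basal arrays above background. CDKN1A lost its call with the slide row as a term (adjusted p = 0.0644), where its change of 2.48 rests on co-culture array 1 alone. The change within the first slide row, which holds the same array, was also 2.48. Slopes on the stromal index were 1.1 for CDKN1A and 0.85 for PLK2, and the 9 members of this list at least 2-fold higher had a median slope of 0.21, with 33.3% over 0.5. G2 and mitosis genes rose in 14 of 26 cases and fell in 3, or 16 and 3 adjusted over the list alone (median 0.43; camera adjusted p = 0.00239; adjusted p = 0.404 with an estimated correlation). CDK1, UBE2C and TOP2A rose by 1.9 ± 0.12, 1.64 ± 0.16 and 1.47 ± 0.21 (SE), while the mitotic transcription factor FOXM1 fell by 1.78 ± 0.13 (SE). Of 27 S phase genes, 2 rose and 12 fell, or 2 and 10 adjusted over the list alone, without a call for the list (median -0.31; camera adjusted p = 0.516). TK1, thymidine kinase, rose by 1.44 ± 0.14 and POLA1 and E2F1 fell by 1.6 ± 0.1 and 1 ± 0.12 (SE). The brightest probe of MCM7 fell by 1.41 ± 0.15, whereas its 5'-most probe rose by 0.5 (adjusted p = 0.00704). Histone genes fell in 9 of 17 cases and rose in 1, also adjusted over the list alone (median -0.57; camera adjusted p = 0.203), with H4C5 down by a log2 change of -2.22 ± 0.21, H3C2 by -1.45 ± 0.14, H4C2 by -1.42 ± 0.21 and H2AC20 by -1.29 ± 0.15 (SE). Labelling started from an oligo-dT primer, so histone mRNA without a poly(A) tail is poorly covered and these values do not give total histone mRNA. Probes of histone genes, of HSPA1A and HSPA1B and of SERPINB3 and SERPINB4 may cross-hybridise with their paralogs. Immediate early genes rose in 4 and fell in 7 of 24 cases, also adjusted over the list alone (median 0.14; camera adjusted p = 0.742). IER3 rose by 4.83 ± 0.38, and FOSL1 and FOSL2 fell by 2.3 ± 0.19 and 1.99 ± 0.31 (SE). IER3 stood at 4.38, 4.55 and 5.1 in co-culture replicates 1, 2 and 3, in the order of the stromal index. The 3 immediate early genes at least 2-fold higher had a median slope of 0.34 on it, with 33.3% over 0.5.

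**Figure D3:**
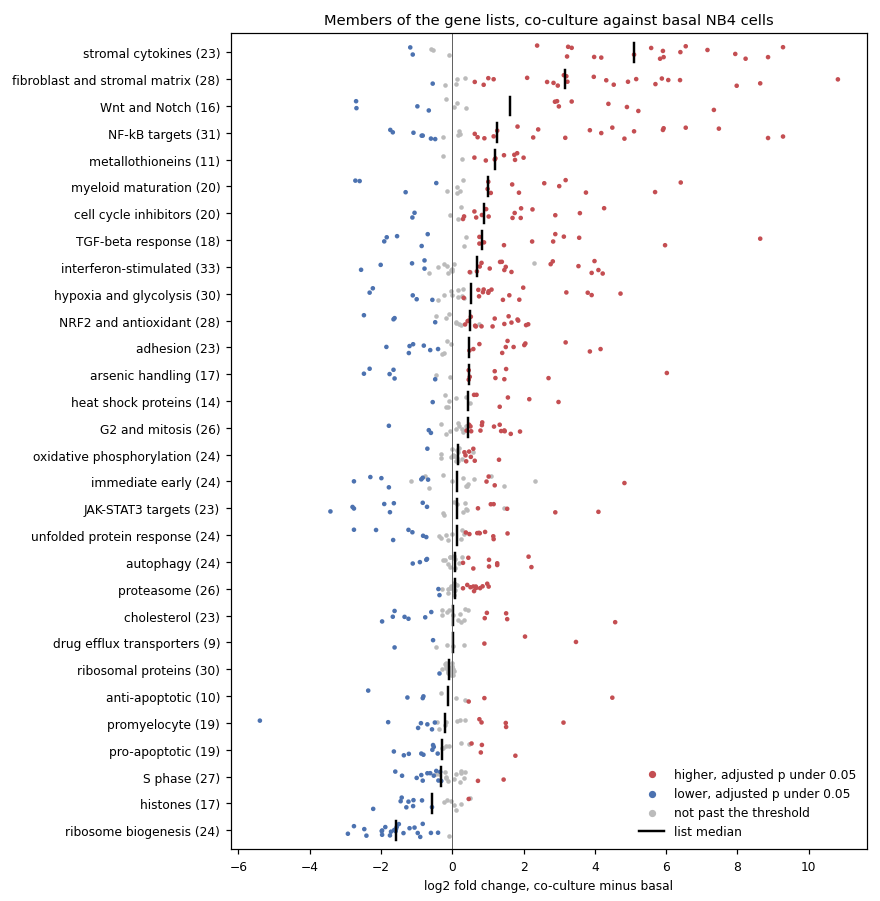
Log2 fold change, co-culture minus basal (horizontal axis), of each measured member (points) of the 30 gene lists (rows, with the number measured), with the list median (black bar). Medians run from -1.58 for ribosome biogenesis to 5.1 for stromal cytokines. Points of genes below background in a group are fitted values, not bounds.

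Metal and oxidant responses rose. Of 11 metallothionein genes, 9 rose and none fell, also adjusted over the list alone (median 1.21; camera adjusted p = 0.000571; adjusted p = 0.41 with an estimated correlation), and these near-identical paralogs cannot be fully separated by their probes. MT1M rose by 2 ± 0.17 (SE; chromosome 16, 56667810 to 56667869), MT1L by 1.82 ± 0.2, MT1E by 1.76 ± 0.18 and MT1B by 1.74 ± 0.2 (SE). The 7 metallothioneins at least 2-fold higher had a median slope of 0.5 on the stromal index. Of 28 NRF2 and antioxidant genes, 16 rose and 4 fell, also adjusted over the list alone (median 0.49; camera adjusted p = 0.00285; adjusted p = 0.232 with an estimated correlation). HMOX1, heme oxygenase, rose by 2.07 ± 0.15, CAT, catalase, by 1.85 ± 0.13 and ME1 by 2.13 ± 0.34 (SE). SLC7A11, the cystine importer, fell by 2.48 ± 0.16 (SE). Genes that handle arsenic split, with 9 of 17 higher and 6 lower, also adjusted over the list alone (median 0.46; camera adjusted p = 0.298), and 7 of them are shared with the antioxidant list. GSTM3, a glutathione transferase, rose by 6.02 ± 0.27 (SE), with a slope of 1.13 on the stromal index against a median of 0.03 for the list's 6 members at least 2-fold higher, and AQP9, an aquaglyceroporin that admits arsenite, was at least 2.31-fold higher. The brightest probe of SLC2A1 fell by 2.32 ± 0.13 (SE), but its 5'-most probe rose by 0.6 (adjusted p = 0.029). Heat shock genes rose in 6 and fell in 1 of 14 cases, also adjusted over the list alone (median 0.45; camera adjusted p = 0.063), led by HSPA1A at 2.98 ± 0.25, BAG3 at 2.16 ± 0.25, HSPA4L at 1.56 ± 0.15 and HSPA1B at 1.33 ± 0.19 (SE). Camera called this list in 7 alternatives, among them quantile scaling (adjusted p = 0.0281) and the mean of all probes (0.0131). Unfolded protein response genes rose in 9 and fell in 7 of 24 cases, or 10 and 8 adjusted over the list alone (median 0.12, mean -0.11; camera adjusted p = 0.697). The chaperone HSPA5 rose by 1.55 ± 0.28, whereas TRIB3, ASNS and EDEM1 fell by 2.76 ± 0.18, 2.14 ± 0.12 and 1.66 ± 0.16 (SE).

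Survival, adhesion and transport lists were not called by camera, while fry, which tests each list by itself, called the anti-apoptotic (adjusted p = 0.0198) and pro-apoptotic (0.00101) lists lower and the adhesion (0.00113) and efflux (0.0407) lists higher. Of 10 anti-apoptotic genes, 3 rose and 4 fell, also adjusted over the list alone (median -0.12, mean 0.07; camera adjusted p = 0.938). BIRC3 rose by 4.49 ± 0.33 and BIRC2 by 0.9 ± 0.21, while BCL2 and XIAP fell by 2.36 ± 0.23 and 1.26 ± 0.13 (SE). BIRC2 lost its call with the slide row as a term (adjusted p = 0.063), where its change of 0.94 rests on co-culture array 1 alone. The change within the first row, which holds the same array, was also 0.94. The 5'-most probe of XIAP, at -0.27, did not pass (adjusted p = 0.187). Of 19 pro-apoptotic genes, 4 rose and 9 fell, also adjusted over the list alone (median -0.29; camera adjusted p = 0.742). BMF rose by 1.77 ± 0.17, and TNFRSF10A and BCL2L11 fell by 1.64 ± 0.23 and 1.22 ± 0.14 (SE). The mean of the BCL2L11 probes, at -0.15, and its 5'-most probe, at -0.03, did not pass. Adhesion genes rose in 12 and fell in 7 of 23 cases, also adjusted over the list alone (median 0.48; camera adjusted p = 0.0694). ICAM1 rose by 3.86 ± 0.19, CD9 by 2.05 ± 0.14 and CDH2, N-cadherin, by 4.16 ± 0.28 (SE), the last measured on 1 of 3 basal arrays. The slope of CDH2 on the stromal index was 1.2, against a median of -0.03 for the 9 adhesion genes at least 2-fold higher. Camera called the adhesion list in 5 alternatives, among them quantile scaling (adjusted p = 0.0388) and the mean of all probes (0.0104). Of 9 measured genes on the efflux list, 3 rose and 2 fell, or 4 and 2 adjusted over the list alone (median 0.01; camera adjusted p = 0.532). MVP, the major vault protein and not itself a transporter, rose by 3.47 ± 0.33 (SE). Of the transporters, ABCC4 rose by 2.04 ± 0.22 and ABCC6 by 0.9 ± 0.19, and ABCC2 fell by 1.62 ± 0.15 (SE). ABCC4 was above background on 2 of 3 basal arrays, and ABCC6 lost its call within the first slide row, at 0.94 (adjusted p = 0.0628).

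Among metabolic genes, those of hypoxia and glycolysis rose in 16 and fell in 5 of 30 cases, also adjusted over the list alone (median 0.53; camera adjusted p = 0.00239; adjusted p = 0.232 with an estimated correlation). ENO2, ALDOC and HK1 rose by 3.91 ± 0.11, 3.8 ± 0.24 and 3.2 ± 0.11 (SE), and the carbonic anhydrase gene CA12 was at least 7.17-fold higher. CA12 had a slope of 1.43 on the stromal index, against a median of -0.08 for the 11 genes of this list at least 2-fold higher. Nuclear genes of oxidative phosphorylation rose in 8 and fell in 1 of 24 cases, or 4 and 1 adjusted over the list alone (median 0.17; camera adjusted p = 0.0322; adjusted p = 0.421 with an estimated correlation), with SDHB up by 1.31 ± 0.11, COX6C by 0.63 ± 0.15 and UQCRC1 by 0.59 ± 0.14, and NDUFS3 down at -0.7 ± 0.11 (SE). Within the first slide row COX6C, UQCRC1 and NDUFS3 lost their calls at changes of 0.55, 0.55 and -0.64 (adjusted p = 0.165, 0.155 and 0.0772). Proteasome genes rose in 11 and fell in 2 of 26 cases, or 10 and 1 adjusted over the list alone (median 0.07; camera adjusted p = 0.0175; adjusted p = 0.41 with an estimated correlation). PSMD12, PSMA4, PSMC2 and PSMC6 rose by 1.02 ± 0.1, 0.98 ± 0.11, 0.85 ± 0.11 and 0.78 ± 0.11 (SE). The 5'-most probe of PSMC2, at 0.55, did not pass (adjusted p = 0.32). Scaling to the array median ended the calls of both lists and turned the proteasome median to -0.06. The oxidative phosphorylation list also lost its call with no filter (camera adjusted p = 0.057) and without co-culture replicate 2 (0.0527), at a median of 0.17 in both. Cholesterol genes rose in 5 and fell in 7 of 23 cases, also adjusted over the list alone (median 0.02, which turned to -0.02 with normexp and -0.11 with median scaling; camera adjusted p = 0.742). MSMO1, a sterol oxidase gene, rose by 4.57 ± 0.23 (SE). Autophagy genes rose in 9 and fell in 4 of 24 cases, or 8 and 4 adjusted over the list alone (median 0.08; camera adjusted p = 0.139, but 0.0281 with quantile scaling and below the threshold in 3 alternatives in all), including WIPI1 at 2.22 ± 0.16, GABARAPL1 at 2.14 ± 0.15, and MAP1LC3A and GABARAPL2 at 1.26 ± 0.19 and 1.26 ± 0.16 (SE).

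Many targets of developmental signalling rose. TGF-beta response genes rose in 11 and fell in 5 of 18 cases, also adjusted over the list alone (median 0.83; camera adjusted p = 0.0125; adjusted p = 0.254 with an estimated correlation). LTBP1 was at least 15.3-fold higher, and ID3 rose by 3.56 ± 0.17 (SE), measured on 1 of 3 basal arrays. The 8 members at least 2-fold higher had a median slope of 0.36 on the stromal index, with 50% over 0.5, from ID3 at 0.11 to LTBP1 at 1.43 among those named. Wnt and Notch genes rose in 8 and fell in 4 of 16 cases, also adjusted over the list alone, with a median of 1.63, or 1.41 with bounds (camera adjusted p = 0.049; adjusted p = 0.404 with an estimated correlation). HES4 rose by 7.34 ± 0.36 (SE), and LEF1, HEY1 and DKK1 were at least 8.42-fold, 10.6-fold and 5.75-fold higher. Signal of HES4, LEF1, HEY1 and DKK1 rose from co-culture replicate 1 to 2 to 3, in the order of the stromal index, and DKK1 had a slope of 1.24 on it. The 8 members of the Wnt and Notch list at least 2-fold higher had a median slope of 0.66, with 50% over 0.5. The TGF-beta list lost its call over probes above background on all 7 arrays (camera adjusted p = 0.358). The Wnt and Notch list lost its call in 11 alternatives with the preset correlation. Among them were that filter (camera adjusted p = 0.714, median 0.04) and normexp (0.0732, median 0.58). Quantile scaling (0.0604, median 1.61) and leaving out basal replicate 2 (0.0785, median 1.45) also ended it, with medians near that of the main fit.

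Among the named genes, the largest fitted decrease was that of RGL4, a guanine nucleotide exchange factor for Ral, at -6.33 ± 0.57 (SE). Genes below background in co-culture may have fallen more. Other large decreases were ZNF469 at -5.59 ± 0.18, AFF2 at -5.59 ± 0.27, CTSG, NCOA5, a nuclear receptor coactivator, at -5.29 ± 0.23, ZNF407-AS1 at -5.32 ± 0.62 and ADAM1 at -5.25 ± 0.27 (SE). RGL4, NCOA5 and ZNF407-AS1 were above background on 1 of 4 co-culture arrays and ZNF469 on 3. CHRNA10, a nicotinic receptor subunit, was at least 13-fold lower, SPATA41 at least 10.7-fold, GPA33 at least 9.41-fold, ZNF831 at least 9.25-fold and ZNF790 at least 8.2-fold lower. In 10 of these 12 genes the probe lay more than 2000 nt into the transcript.

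Changes depended on where along its transcript a probe lay. For 1233 pairs of probes on the same RefSeq mRNA more than 1000 nt apart and above background on all arrays, the 3'-ward probe's log2 change was lower in 77.4% of pairs, by a median of -0.73. Pairs under 100 nt apart had a median difference of 0. Relative to the mean of both groups, the 3'-ward over 5'-ward signal deviated by 0.27 to 0.43 on the log2 scale in the 3 basal arrays and by -0.39 to -0.33 in the 4 co-culture arrays. Of 1062 pairs in which both probes passed, 206 passed in opposite directions, and in 190 of these the 5'-ward probe was the higher. Among RefSeq mRNA probes that passed, 64.5% were higher in co-culture when the probe began between 500 and 1000 nt into the transcript, against 19% beyond 6000 nt. Unlike the pairs, these are different transcripts, and only long ones reach beyond 6000 nt, so position and transcript length are confounded there. Removing the trend over probe position, which has the same limit, left ribosome biogenesis at a median of -1.71 and myeloid maturation at 0.77, both still called. It made ribosomal proteins (median -0.4, adjusted p = 0.00527) and histones (median -0.87, adjusted p = 0.0206) called lower and adhesion (0.45, adjusted p = 0.0337) and autophagy (0.26, adjusted p = 0.0456) called higher, and ended the calls of oxidative phosphorylation (adjusted p = 0.679) and the proteasome (adjusted p = 0.468).

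**Figure D4:**
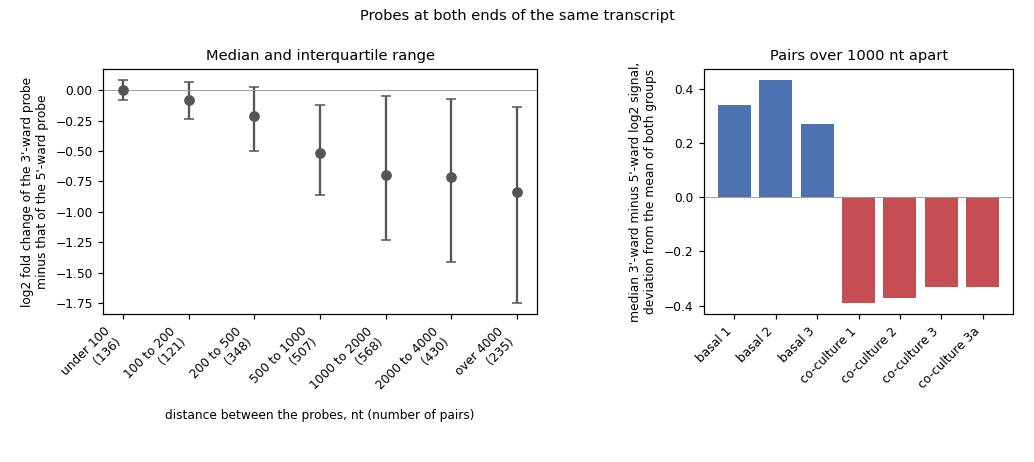
Left, difference in log2 fold change between the 3'-ward and 5'-ward probe of a transcript (vertical axis; point, median; bar, interquartile range) by the distance between them in nt (horizontal axis, with the number of pairs), falling from 0 under 100 nt to -0.84 over 4000 nt. Right, median 3'-ward minus 5'-ward log2 signal on each array for 1233 pairs over 1000 nt apart, as the deviation from the mean of both groups, with all 3 basal arrays above 0 and all 4 co-culture arrays below it.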

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

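More probes were lower than higher under every alternative run. The largest falls in the number of called probes, from 16023, came with the slide row and the 2-fold threshold. With the slide row as a term, which rests the group effect on co-culture array 1, 11032 were called and 6213 of them were lower. Within the first slide row 9650 were called, 4297 higher and 5353 lower, with fewer samples. Adding a change of at least 2-fold to the threshold, which can only remove calls, left 8592, with 3962 higher and 4630 lower. Leaving out each replicate in turn gave 13884 to 15894 called probes and 14 to 16 called lists. Scaling to the array median moved the share of higher calls from 41.7% to 34.2%. The 3 pairs of same-numbered samples had correlated deviations of 0.08, -0.02 and -0.03, so the numbers share no more than a label, and not every sample correlated best with its own number. A fit with the number as replicate block called 15028 probes and 16 lists.

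Of 30 lists, 15 were called with a preset correlation, 0 with an estimated one and 26 with fry, which tests each list by itself. With 4 residual degrees of freedom the estimated correlations ran from -0.11 to 0.7. The JAK-STAT3 and unfolded protein response lists, with medians of 0.13 and 0.12, leaned upward in camera and were called downward by fry. With the 5'-most probe, added after seeing the data, the changes of 4 named genes turned: OSM to 0.05, SLC2A1 to 0.6, MCM7 to 0.5 and MYC to 0.84. The cause was not tested gene by gene. Signal over background limits the bounds given for genes not measured in a group.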

Other observations

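Most transcripts encoded by the mitochondrial genome were lower in co-culture. Of 13 probes for them, 11 passed as lower, from -0.66 ± 0.14 (SE) for ND4L to -4.52 ± 0.21 for CYTB, cytochrome b, and the 2 probes of ND4 did not pass, with changes of 0.07 ± 0.2 and -0.11 ± 0.18 (limma adjusted p = 0.781 and 0.604). These genes and the ones in the next sentences were chosen after their values were seen. A few genes outside the lists of the report also rose strongly, and no test of them as a group was run. CCL7, a monocyte chemokine, and MMP12, macrophage elastase, were below background in basal cells and at least 65.7-fold and 27.8-fold higher in co-culture. SPP1, osteopontin, rose by 6.75 ± 0.27 on the log2 scale, the complement gene C3 by 6.51 ± 0.17 and ALOX5AP by 5.99 ± 0.17 (SE). Slopes of these 5, picked from the genes at least 2-fold higher, on the stromal index lay between -0.23 and 0.1.

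The tests below that use the stromal index, the dilution of NB4 RNA, GC content and distance between probes were chosen after the results were seen, as were both alternatives for probe position. The other tests were written beforehand, except that the probe pairs behind the test of bright signals were chosen after seeing the data. For the cytokine slope of 0.83, the rule that names its outcome was also changed after the slopes were seen: as first written it could only reject carry-over or leave it open, and it left it open. The changed rule lets a median slope near 1 count as what carry-over predicts, so that outcome carries little weight.

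Stromal and cytokine genes that NB4 cells lack at baseline rose with a shared replicate pattern. The median change of the risen fibroblast, cytokine and myeloid genes stayed at 2.34 or higher on the log2 scale under every scaling, which says little because these genes were selected for rising. The medians of the whole fibroblast and cytokine lists stayed at 1.51 and 3.16 or higher, so their rise did not depend on which scaling was used. The lists were fixed beforehand, but the filter also kept members for their co-culture signal alone, which favours a rise. Over probes above background on every array, the fibroblast median was 0.94 with the main scaling. Other scalings were not run with that filter, so scaling was not tested free of this selection. A candidate explanation is RNA of HS-5 cells carried over with the NB4 cells. Cytokine genes below background in basal cells followed the fibroblast index with a median slope of 0.83 (interquartile range 0.8 to 1.02), as a varying share of HS-5 RNA would give, and abundant stromal transcripts such as MMP1 and COL6A1 stood at 8.97 and 5.57 in co-culture, but basal cells also had 14 of 28 fibroblast and 12 of 23 cytokine genes above background on every array. Risen myeloid maturation genes had a lower median slope of 0.08 (interquartile range over genes -0.02 to 0.17). This does not exclude carry-over for them, because every slope rests on the same few co-culture replicates and has no error. A constant basal signal, which most of these genes had, also lowers a slope. COL1A1 at -0.22 and CXCL6 at -0.79 were the only negative slopes among the index and cytokine genes. A response of NB4 cells to stroma may underlie the myeloid part. Induction of stromal genes in NB4 in proportion to contact also stays open.

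The fall of ribosome biogenesis genes was set against dilution by HS-5 RNA, probe position and scaling. Promyelocyte genes lay above them by a difference in medians of 1.39 (two-sided permutation p = 3e-05 over genes, 19 against 24, which are not independent replicates). Dilution must lower promyelocyte genes as much only if HS-5 cells lack them and nothing else moved them. HS-5 RNA alone was not measured, and 5 of the promyelocyte genes rose and 7 fell. With the 5'-most probe of each gene, the list still lay -1.32 from the median of all genes, but this says little, because 17 of 24 genes kept the same probe. In the 7 whose probe changed the median moved from -1.63 to -0.66, with 5 still lower. With the trend over position removed, the list median was -1.71 and the list was still called. The highest list median under any scaling was -1.34. Scaling alone is therefore unlikely to give the fall, and an average trend over position did not give it. The promyelocyte comparison speaks against dilution only as far as those genes did not change on their own, so dilution is not excluded. The choice of probe may set the size of the fall in single genes such as MYC. How much is biological stays open.

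Lower change at 3'-ward than at 5'-ward probes was not limited to bright signals, since pairs with the dimmer probe 3'-ward had a median of -0.64. It did not follow GC content (Spearman's rho 0.04 across pairs, which are not independent replicates). It grew with distance (rho -0.32). Differences in RNA integrity or labelling length between the groups and shorter 3' ends in co-cultured cells could both give this, and they cannot be told apart, because every basal and every co-culture array fell on its own side.

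The 3 replicates against 3 allow 10 splits, too few for a share under 0.05. The real split called 16023 probes and 1 split, the real one, gave as many, against at most 0 for the others.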
